A study of Mus musculus with 16 samples.

How the data were processed

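T cell receptor (TCR) sequences of single regulatory T cells (Treg), sorted as CD25-positive cells from male mice that carry GFP at the Nfil3 locus, were read from 16 libraries, 1 library per population and mouse. In mice 1 and 2 the populations were 3 spleen sorts (Nfil3(GFP)-negative Klrg1-negative, called double-negative here; Nfil3(GFP)-positive Klrg1-negative, which the descriptions call progenitor; Nfil3(GFP)-positive Klrg1-positive) and Klrg1-positive cells of skin, fat and colon. In mouse 3 they were Nfil3(GFP)-positive cells of the inguinal lymph node, the mesenteric lymph node, skin and colon. Groups were taken from the sample titles. The protocol text names skin but neither fat nor colon for mice 1 and 2, and gives a tissue gate on Nfil3(GFP) without Klrg1, so the titles were followed and the Klrg1 gate of the tissue sorts rests on the titles alone. The mouse number pairs the samples by design, because all libraries with 1 number come from a single animal.

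The submitters' processing notes name Cell Ranger 2.2.0, R 3.4.2 and the builds mm10 and GRCm38, without saying what each was used for. Per the labels the libraries were droplet-based TCR enrichments, and the deposited tables join the libraries of several samples. Per the file headers, the frequency of a clonotype is in counts of cells, UMIs and reads per chain are in counts, and library metrics (estimated cells, read pairs, median UMIs) are in counts. The deposited proportion of a clonotype is a fraction of the estimated cells of its library, which was checked by multiplying it back to the cell count in all 16 libraries. The deposited paired clonotype diversity is a score of the pipeline and was not used in a comparison. CDR3 sequences and segment calls are deposited as text, a unit of other kind.

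A clonotype was kept if it held exactly 1 TRB chain and 1 or 2 TRA chains, and 2 clonotypes were called the same if the nucleotide CDR3 sequences of all their chains were identical. This kept 42.8% to 71.7% of the cells with a clonotype, that is 110 to 6854 cells per library. It leaves out cells with more than 1 TRB or more than 2 TRA chains, as droplets with 2 cells would show, and no other doublet filter was used. Chain dropout and additional TRA chains divide the cells of 1 TRB over several clonotypes, so identity by TRB alone was among the alternatives. Cells are not replicates. The replicate unit is the mouse (n = 2 for the comparisons of mice 1 and 2, n = 1 for mouse 3), and means are given with the SD over the 2 mice.

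Overlap of 2 libraries was measured as the Morisita-Horn index and as the percent of cells of a library whose clonotype was found in the other. Because a larger library finds more clonotypes, the library searched was thinned to the smallest of its set by the hypergeometric expectation: 323 cells in mouse 1 and 480 cells in mouse 2 for the spleen libraries, 203 and 188 cells for the tissue libraries, and 110 cells for the lymph nodes of mouse 3. Clonal expansion (percent of cells in clonotypes of 2 or more cells) and diversity (exponential of the Shannon entropy) were taken at 188 cells in all 12 libraries of mice 1 and 2. CDR3 measures were means over distinct clonotypes: TRB CDR3 length, the number of residues F, I, L, M, V, W, Y or C at positions 6 and 7 counted from the conserved cysteine as 1, the percent of TRA chains with a TRAJ number of 30 or lower, and the percent of TRB chains with a TRBJ2 segment. Cells with TRAV11 or TRAV11D joined to TRAJ18 were counted as invariant NKT-type and cells with TRAV1 joined to TRAJ33 as MAIT-type.

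The tests were exact permutation tests. Overlap within against between mice used 32 labelings (one-sided, smallest p 0.03125). For sharing of the tissues with the spleen populations, Klrg1-positive minus double-negative alone was tested. It used 36 labelings of the 3 spleen labels within mice (one-sided, smallest p 0.0278), in which the progenitor label moves too. Permuting only the 2 labels of a difference in 2 mice cannot give a p below 0.25, for this difference as for the others. The 8 library-level measures used 10395 partitions of the 12 libraries into 6 pairs (smallest p 9.62e-05), with Benjamini-Hochberg adjustment over the 8 p of 1 setting (the first p where an alternative does not apply to a measure), and 720 labelings within mice where the mouse is a block. Segment usage was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, 1 model for the 12 libraries) on the number of distinct clonotypes per TRAV, TRAJ, TRBV and TRBJ segment, for 6 contrasts. edgeR's expression filter left 46 of 167 segments (7 TRAV, 12 TRAJ, 16 TRBV and 11 TRBJ), with library totals of 290 to 18452 and a threshold of 0.05 on the adjusted p. Shares given for 1 library carry 95% exact (Clopper-Pearson) intervals. Where 0 cells were found, the limit given is 3 counts of the total. Intervals and limits cover counting error only. Other computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9. Segment positions are from GENCODE on GRCm38.

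The thinning was checked against 200 random draws in 3 comparisons, and the largest deviation was 1.06 standard errors. The segment test was tested on simulated data, 10 sets per contrast with 20 segments changed. Counts were drawn independently per segment with the common dispersion of the model (0.00655), and the changed segments were chosen to leave library totals nearly unchanged. It recovered 64.0% to 100% of 4-fold changes and 22.0% to 94.0% of 2-fold changes, and 2.25% to 7.73% of its calls were false. In the real libraries the same chain recurs in several clonotypes, which the simulation left out. These rates therefore need not hold for the real data.

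The tests, the clonotype definition, the alternatives and the rule for naming items were chosen before the data were examined, except where said otherwise. The rule names, per contrast, up to 12 segments past the threshold with the largest absolute log2 fold change that changed the same way in both mice, or where fewer than 4 pass, the 4 with the smallest p. It also names, in each of mice 1 and 2, the 4 clonotypes with the most tissue cells among those found in the progenitor library and a tissue, and in mouse 3 the 2 with the most tissue cells for each node and tissue pair. TRAV11, TRAJ18, TRAV1 and TRAJ33 are named always. Alternatives were amino acid identity, TRB identity, every paired clonotype, every clonotype, no thinning, clonotypes in place of cells or the reverse, 3 cells as the bound of expansion, the inverse Simpson index, the Jaccard index, clonotypes of a single cell left out, the mouse as a block, DESeq2 1.42.0, TMM scaling, no filter, and each mouse or library left out. Added after seeing the data were fat left out of the tissue mean, also without thinning, a spleen library that held 2 or more cells of the clonotype, each distinct chain counted once per library, also with the mouse as a block, and near-identical TRAV copies merged. Left out of the comparisons were 25 further library metrics (base quality, mapping and contig shares) and 4 further chain columns.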

Results

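The study set TCR clonotypes of spleen Treg that differ in Nfil3(GFP) and Klrg1, a marker of the tissue-type Treg its labels name, beside those of Treg in skin, fat and colon of the same animals. Across the 16 libraries 48959 cells had a clonotype and 25262 were kept. In mouse 1, 4460 double-negative, 1307 progenitor and 323 Klrg1-positive spleen cells were kept, with 203 skin, 806 fat and 266 colon cells. In mouse 2 the numbers were 4267, 3881 and 480 for the spleen, and 268, 331 and 188 for skin, fat and colon. Mouse 3 gave 110 inguinal node, 6854 mesenteric node, 169 skin and 1349 colon cells. Depth differed between libraries: 979 to 19798 read pairs per estimated cell, median UMIs per cell of 2 to 10 for TRA and 3 to 17 for TRB.

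The first question was whether clonotypes are shared between populations of an animal beyond what different animals share. Populations of the same mouse shared clonotypes, and populations of mouse 1 shared none with those of mouse 2. In mouse 1, 14 of the 15 population pairs had at least 1 clonotype in common, and in mouse 2, 13 of 15, while none of the 36 pairs of a mouse 1 with a mouse 2 library had any. The largest overlaps were those of spleen Klrg1-positive cells with skin in mouse 1 (Morisita-Horn index 0.211) and with spleen progenitor cells in mouse 2 (0.207), where a value of 1 means identical repertoires. The mean index was 0.0254 within mouse 1 and 0.0351 within mouse 2, 0.0302 over both, and 0 between them (exact permutation test, one-sided, p = 0.03125, the smallest this design can give). With 0 between the mice no swap of labels can raise the difference, so this p adds nothing to the counts of pairs. Of the 48 pairs of a library of mice 1 or 2 with a library of mouse 3, 2 shared a clonotype. It was the same clonotype in both pairs (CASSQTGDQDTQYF with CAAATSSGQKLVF), with 3 colon cells in mouse 1 and 1 mesenteric node and 2 colon cells in mouse 3.

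The second comparison asked how far the populations were clonally expanded. Expansion was lowest in the double-negative spleen cells and highest in fat. At 188 cells per library, 0.0705 ± 0.0599% (SD, n = 2 mice) of double-negative cells belonged to clonotypes of 2 or more cells, against 16.8 ± 2.08% of progenitor and 31.6 ± 1.68% of Klrg1-positive spleen cells. The tissue values were 36.3 ± 2.78% in colon, 46.3 ± 0.906% in skin and 83.3 ± 0.315% in fat. Here differences between neighbouring populations exceeded the spread between the mice, the smallest being that of colon to spleen Klrg1-positive cells, at 34.4 and 38.3% against 30.4 and 32.8%. Double-negative cells stayed lowest and fat highest in every alternative, but the order of colon, skin and spleen did not hold in each. Counting clonotypes of 3 or more cells, colon stood at 16.4 ± 5.19%, below the Klrg1-positive spleen cells at 21.1 ± 2.14%. Without thinning, progenitor cells, Klrg1-positive spleen cells and colon stood at 37.99 ± 9.79%, 38.95 ± 4.73% and 38.89 ± 0.831%, and in mouse 2 progenitor cells (44.9%) were above Klrg1-positive ones (42.3%). With every paired clonotype, colon at 30.4 ± 8.05% and Klrg1-positive spleen cells at 23.1 ± 4.67% differed by less than the spread. Colon and skin (32.3 ± 2.29%) did so too, with colon at 36.1% above skin at 33.9% in mouse 2, and with every clonotype, single-chain ones included, they stood at 30.4 ± 4.94% and 33.5 ± 0.937%. The population means differed over a span of 83.2 percentage points (exact permutation test, p = 9.62e-05, the smallest possible, adjusted p = 0.00077). With the mouse as a block the p was also the smallest possible, 0.00139 (adjusted p = 0.0111).

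**Figure D1:**
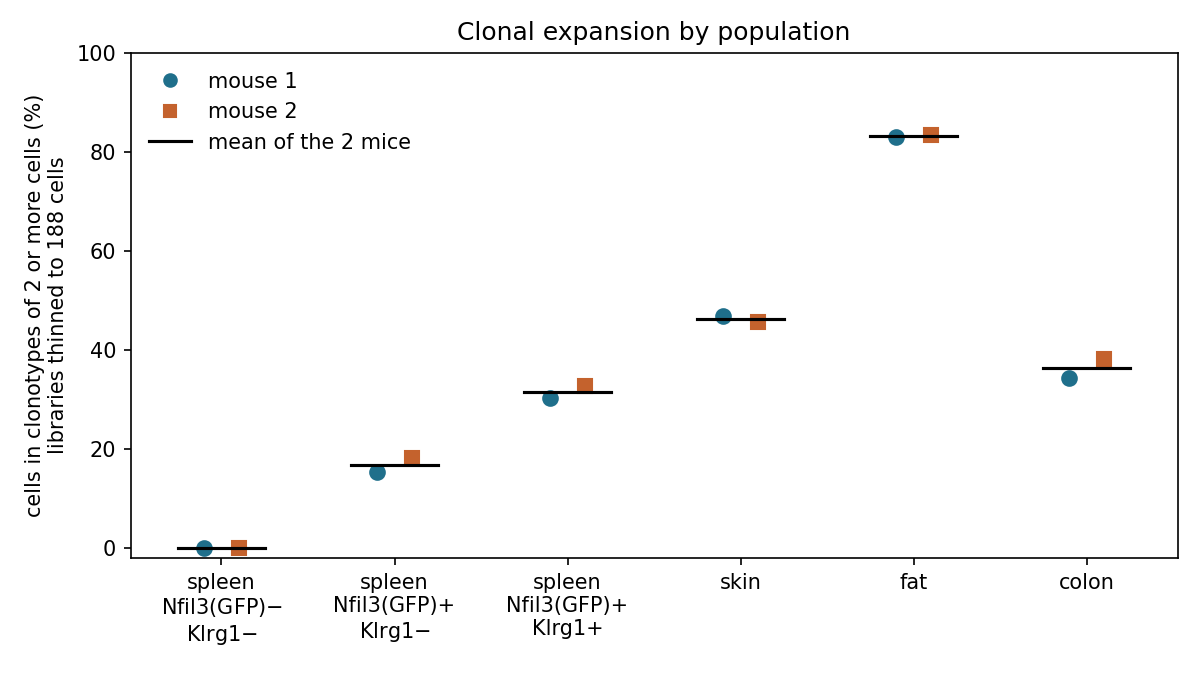
Percent of cells in clonotypes of 2 or more cells (vertical axis) in the 6 populations (horizontal axis), with each library thinned to 188 cells; circles are mouse 1, squares mouse 2, and lines the mean of the 2 mice. Both mice lie near 0 in the double-negative spleen cells and near 83% in fat.

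Diversity was highest in double-negative cells and lowest in fat, with colon above the Klrg1-positive spleen cells by less than the spread between the mice; without thinning colon was below them (143.6 ± 18.6 against 188.4 ± 7.86). The effective number of clonotypes among 188 cells was 187.9 ± 0.0780 in double-negative, 154.2 ± 10.6 in progenitor and 114 ± 23.8 in Klrg1-positive spleen cells, 126.7 ± 5.33 in colon, 90.3 ± 24.7 in skin and 9.55 ± 3.08 in fat (SD, n = 2). These means differed as well (exact permutation test, p = 0.000866, adjusted p = 0.00346; with the mouse as a block p = 0.00278, adjusted p = 0.0111).

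A single TRB made up most of the kept fat cells of mouse 1, and in mouse 2 about as many as all other TRBs together. In mouse 1 the TRB CDR3 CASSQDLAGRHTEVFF (TRBV2, TRBJ1-1) was carried by 609 of 806 kept fat cells (75.6%, exact interval 72.4 to 78.5%). Among all fat cells with a clonotype, those not kept included, 780 of 1310 (59.5%) carried it. In kept cells it was paired with the TRA CDR3s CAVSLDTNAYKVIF and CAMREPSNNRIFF in 428 cells and with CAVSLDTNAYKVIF alone in 146. In mouse 2 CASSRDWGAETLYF (TRBV12-2, TRBJ2-3) was carried by 170 of 331 fat cells (51.4%, 45.8 to 56.9%), 141 of them with the TRA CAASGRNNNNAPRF. The largest clonotype of the progenitor library of mouse 2, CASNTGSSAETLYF with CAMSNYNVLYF, had 181 cells there and 14 among the Klrg1-positive spleen cells. The largest among the Klrg1-positive spleen cells of mouse 2, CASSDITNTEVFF with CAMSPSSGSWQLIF, had 69 cells there and 28 in the progenitor library. These clonotypes were chosen after their values were seen.

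The comparison the descriptions point to is which spleen population shares clonotypes with the tissues. Averaged over the tissues and at equal library size, Klrg1-positive spleen cells shared most, progenitor cells less, and double-negative cells least. With spleen libraries thinned to equal size within a mouse, 16.6 ± 12.7% (SD, n = 2 mice) of tissue cells, averaged over skin, fat and colon, had their clonotype among the Klrg1-positive spleen cells. The mean was 1.19 ± 0.0555% for progenitor and 0.0744 ± 0.0419% for double-negative cells. By distinct clonotypes the 3 means were lower or close, at 3.70 ± 1.77%, 0.678 ± 0.183% and 0.0871 ± 0.0806%. Where the spleen library had to hold 2 or more cells of the clonotype, an alternative chosen after seeing the data, they were 5.54 ± 0.0545%, 0.586 ± 0.447% and 0.0320 ± 0.0453%. Klrg1-positive minus double-negative was 16.5 ± 12.7 percentage points, 25.6 in mouse 1 and 7.55 in mouse 2 (exact permutation test, one-sided, p = 0.0278, the smallest possible), and positive in 6 of 6 combinations of mouse and tissue. Progenitor minus double-negative was 1.11 ± 0.0136 points, positive in 5 of 6 and 0 in fat of mouse 2. Klrg1-positive minus progenitor was 15.4 ± 12.7 points (24.5 in mouse 1, 6.43 in mouse 2) and positive in 6 of 6. In colon, however, the Morisita-Horn index gave the reverse order in both mice, as given below. The last 2 differences were not tested. Permuting their 2 labels alone could not give a p below 0.25, and the labelings of all 3 spleen labels, used for the first difference, were not applied to them.

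Counted by cells, skin gave close values in both mice. Of skin cells, 19.7 and 20.5% (mice 1 and 2) had their clonotype among the Klrg1-positive spleen cells. Among progenitor cells it was 2.45 and 2.16%, and among double-negative cells 0.107 and 0.0792%. By distinct clonotypes the Klrg1-positive values were 6.57 and 3.75%. In mouse 2, 35 of the 55 skin cells that matched Klrg1-positive spleen cells belonged to 1 clonotype, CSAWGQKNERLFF with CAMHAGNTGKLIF. The close values by cells thus rest in part on 1 clone. In colon the values by cells were 1.504 and 2.13%, 0.953 and 1.51%, and 0.0272 and 0.233%. The Klrg1-positive colon values rest on 4 of 266 cells (exact interval 0.411 to 3.81%) and 4 of 188 (0.583 to 5.36%). By distinct clonotypes colon of mouse 1 alone turned, with 1.03% among Klrg1-positive and 1.31% among progenitor cells. By the Morisita-Horn index colon turned in both mice, and skin and fat in neither. It was 0.00989 and 0.00777 for colon with progenitor cells, against 0.00553 and 0.00395 with Klrg1-positive spleen cells. In fat the values by cells were 55.6 and 0.302% for the Klrg1-positive and 0.0307 and 0% for the progenitor spleen cells. For double-negative cells they were 0% in both mice. The 0.302% of mouse 2 is 1 of 331 cells (exact interval 0.00765 to 1.67%), and its progenitor zero allows up to 0.906%. Of 806 and 331 fat cells, 0 matched any of the double-negative cells even without thinning, which allows shares of up to 0.372% and 0.906%. The fat value of mouse 1 rests on the 428 cells of its largest clonotype, of which the Klrg1-positive spleen library held 1 cell, and 5.29% of the other fat cells matched that library. Without fat, an alternative chosen after seeing the data, the Klrg1-positive mean was 10.96 ± 0.510%.

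**Figure D2:**
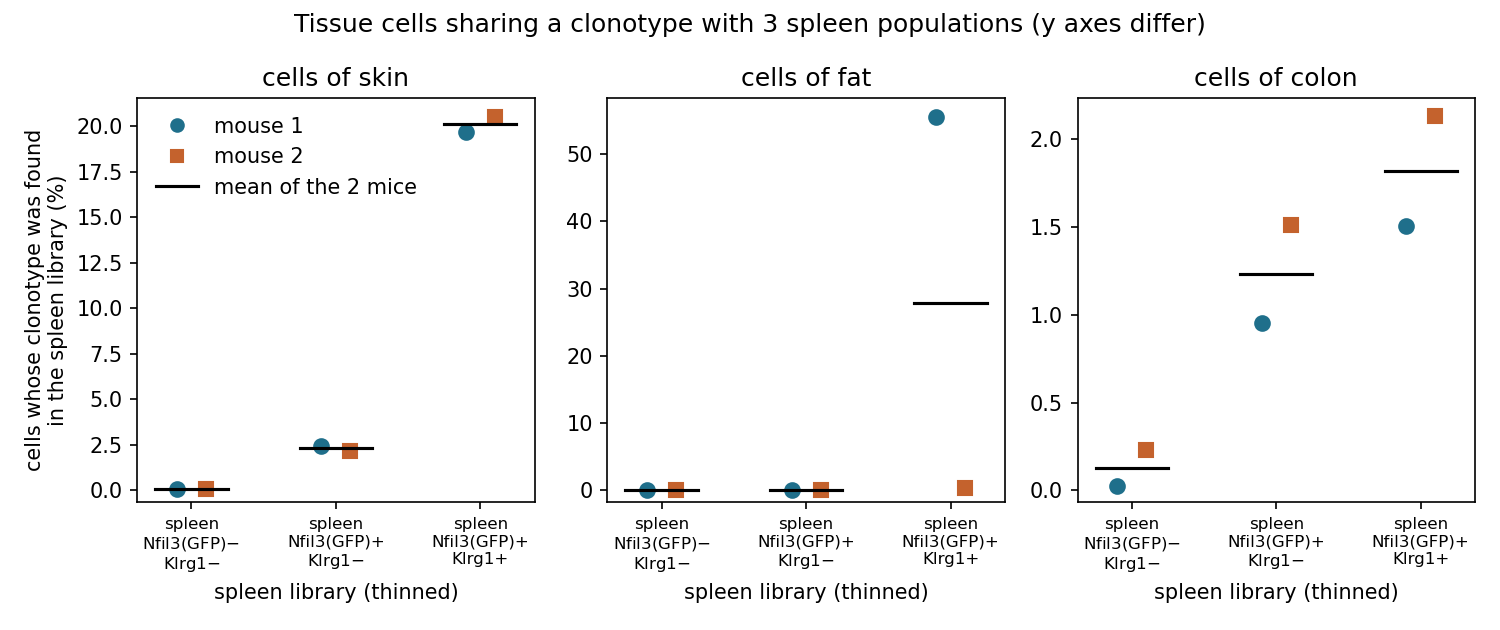
Percent of skin, fat and colon cells (3 panels with different vertical axes) whose clonotype was found in each of the 3 spleen populations, thinned to 323 cells in mouse 1 and 480 in mouse 2; circles are mouse 1, squares mouse 2, and lines their mean. Skin values rise from 0.107 and 0.0792% to 19.7 and 20.5%, and fat of mouse 1 stands at 55.6%.

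Thinning matters here, because the progenitor libraries were larger than the Klrg1-positive ones. Without it, progenitor cells matched 2.68 and 8.20% of tissue cells in mice 1 and 2 and Klrg1-positive cells 25.6 and 7.65%, so the order of the 2 turned in mouse 2. Klrg1-positive minus double-negative was about as large without thinning, 15.99 against 16.55 points, and its exact permutation p rose from 0.0278 to 0.0556, as progenitor cells came above Klrg1-positive ones in mouse 2.

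Clonotypes found both in the progenitor library and in a tissue numbered 6 in mouse 1 and 9 in mouse 2. Of these, 2 and 3 were also among the Klrg1-positive spleen cells, and 1 and 0 among the double-negative cells. In mouse 1, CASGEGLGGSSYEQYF with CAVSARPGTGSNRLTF was seen in 2 progenitor, 7 spleen Klrg1-positive and 6 skin cells. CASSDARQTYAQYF with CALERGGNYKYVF was seen in 1 progenitor, 2 spleen Klrg1-positive, 5 skin and 1 fat cell. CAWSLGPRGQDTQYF with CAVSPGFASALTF had 3 progenitor, 2 skin and 1 colon cell, and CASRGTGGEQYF with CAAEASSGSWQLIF had 11 progenitor, 1 double-negative and 1 colon cell. In mouse 2, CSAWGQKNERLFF with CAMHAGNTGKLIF was the largest skin clonotype, with 35 skin, 2 colon, 2 spleen Klrg1-positive and 1 progenitor cell. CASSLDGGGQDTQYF with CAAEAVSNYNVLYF had 9 skin, 1 spleen Klrg1-positive and 1 progenitor cell. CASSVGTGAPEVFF with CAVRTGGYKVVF had 8 colon and 1 progenitor cell, and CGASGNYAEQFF with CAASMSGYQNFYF had 4 progenitor and 1 colon cell.

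Tissues of a mouse also shared clonotypes with each other. Averaged over the 6 ordered pairs of skin, fat and colon, 10.996% of cells in mouse 1 and 22.8% in mouse 2 had their clonotype in another tissue (mean 16.9 ± 8.36%, SD, n = 2, not tested). Fat cells matched most: 19.7 and 51.2% of them (mice 1 and 2) in skin and 40.7 and 54.4% in colon. Skin cells matched fat at 3.09 and 5.27% and colon at 1.13 and 19.4%. Colon cells matched skin at 0.752 and 3.94% and fat at 0.565 and 2.73%. The fat values come from few clonotypes. In mouse 1, 428 of the 430 fat cells that matched the whole colon library belonged to 1 clonotype, which colon held as 1 cell, and by distinct clonotypes the mean over pairs was 2.54%.

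Mouse 3 set the lymph nodes draining skin and gut beside skin and colon. Skin cells matched the inguinal node, and colon cells matched the mesenteric node when it was searched whole. Of 169 skin cells, 27 (16.0%, exact interval 10.8 to 22.4%) had their clonotype among 110 inguinal node cells and 7 (4.14%, 1.68 to 8.35%) among 6854 mesenteric node cells. Of 1349 colon cells, 167 (12.4%, 10.7 to 14.3%) were found in the mesenteric and 11 (0.815%, 0.408 to 1.45%) in the inguinal node. Thinned to 110 cells, the mesenteric node matched 0.0665% of skin and 0.428% of colon cells. Inguinal minus mesenteric was then 15.9 points in skin and 0.387 in colon, a difference of differences of 15.5 points. This depended on the clonotype definition: it was 7.63 points with every paired clonotype (8.01 in skin), 8.43 with every clonotype (8.72), 7.36 by distinct clonotypes (7.94) and 23.1 by TRB alone (23.5). Without thinning it was 23.4 points, but the colon difference turned to -11.6 points, where 6854 mesenteric and 110 inguinal cells were searched. A mesenteric preference of colon thus cannot be told from library size. It was absent at equal size and from the node side, as given below. The Morisita-Horn index of colon was about equal, 0.00871 with the inguinal and 0.00894 with the mesenteric node. With 1 library per group no test was possible.

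**Figure D3:**
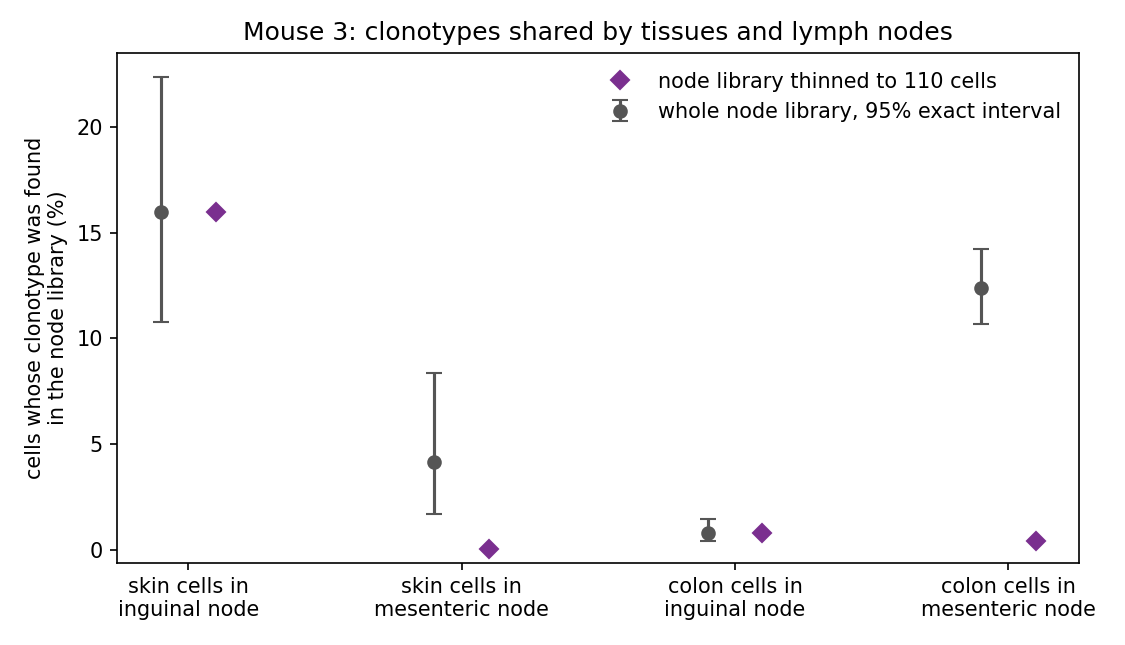
Percent of skin and colon cells of mouse 3 whose clonotype was found in the inguinal or mesenteric node library (vertical axis); circles with bars are whole libraries with 95% exact intervals for counting error, and diamonds the node library thinned to 110 cells. Skin with the inguinal node stands at 16.0% either way, while colon with the mesenteric node drops from 12.4% to 0.428%.

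Searched from the node side, 10 of 110 inguinal cells (9.09%, 4.45 to 16.1%) matched skin and 8 (7.27%, 3.19 to 13.8%) matched colon. Of 6854 mesenteric cells, 2 (0.0292%, 0.00353 to 0.105%) matched skin and 180 (2.63%, 2.26 to 3.03%) colon. Both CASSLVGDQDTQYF with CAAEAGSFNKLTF and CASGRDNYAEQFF with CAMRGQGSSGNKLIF had 5 skin cells and were found in the inguinal node (1 and 2 cells) and colon (2 and 1 cells). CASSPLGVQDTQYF with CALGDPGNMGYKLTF was found in 1 mesenteric and 2 skin cells, and with the additional TRA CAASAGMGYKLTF in 1 inguinal, 1 mesenteric and 5 skin cells. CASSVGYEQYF with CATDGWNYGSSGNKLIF had 20 colon and 1 mesenteric cell, and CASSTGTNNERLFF with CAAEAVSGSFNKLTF had 15 colon and 3 mesenteric cells.

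Segment usage asked whether the populations draw on different germline segments. Between progenitor and double-negative cells of the spleen, 0 of 46 segments passed in edgeR (2 at an unadjusted p under 0.05), and 2 passed in DESeq2, TRBV31 and TRBV12-1. TRBV31, the V segment that lies in inverted orientation downstream of the constant genes (chromosome 6, 41557691 to 41558452, minus strand, GRCm38), made up 4.12 ± 0.241% of progenitor and 6.42 ± 0.358% of double-negative TRB chains (SD, n = 2; log2 fold change -0.69, SE 0.20, edgeR adjusted p = 0.110), lower in both mice. TRBV12-1 (chromosome 6, 41113550 to 41114067) stood at 4.95 ± 0.643% and 2.96 ± 0.198% (log2 fold change 0.72, SE 0.32, edgeR adjusted p = 0.784; DESeq2 adjusted p = 3.99e-05; up to 0.998 over the 7 alternatives). TRAJ12 stood at 4.9995 ± 0.185% and 3.89 ± 0.208% and TRBV3 at 11.9 ± 0.685% and 13.2 ± 0.318%, with adjusted p of 0.838 each. Without fat of mouse 1 or of mouse 2 in the edgeR model, 2 and 3 segments passed, TRBV31 (adjusted p = 0.00266 and 0.00230) and TRBV12-1 (0.00338 and 0.00230) among them. Counting each distinct chain once per library, an alternative chosen after seeing the data, TRBV31 passed at -0.65 (edgeR adjusted p = 0.00441; 0.000839 to 0.998 over the 9 alternatives).

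Between Klrg1-positive and progenitor spleen cells, TRBV12-1 alone passed in edgeR. It was lower, at 0.467 ± 0.661% against 4.95 ± 0.643% (SD, n = 2; log2 fold change -3.24, SE 0.83, edgeR adjusted p = 0.0368), in both mice. All 3 such clonotypes among the Klrg1-positive cells were in mouse 2, and the log2 fold change ran from -2.43 without the Klrg1-positive spleen library of mouse 1 to -8.90 (SE 2.63) without that of mouse 2, where a library with 0 is left. The share rests on 3 of 561 against 179 of 3483 chains, a ratio of 0.104 with an exact counting interval of 0.0213 to 0.309. TRBV31 was at 1.87 ± 0.887% (log2 fold change -1.21, adjusted p = 0.465), TRAJ15 at 1.38 ± 0.0439% against 3.50 ± 0.778% and TRBV26 at 6.60 ± 3.44% against 3.74 ± 1.20%, and none of these passed. The TRBV12-1 call ended with the mouse as a block (edgeR adjusted p = 0.282) and with TMM (0.0596), and over 7 alternatives the adjusted p ran from 0.00480 in DESeq2 to 0.979 by cells. It also ended without either double-negative, Klrg1-positive spleen or colon library or the progenitor library of mouse 1 (edgeR adjusted p 0.0942 to 0.989), and the segment was not tested without the progenitor library of mouse 2.

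**Figure D4:**
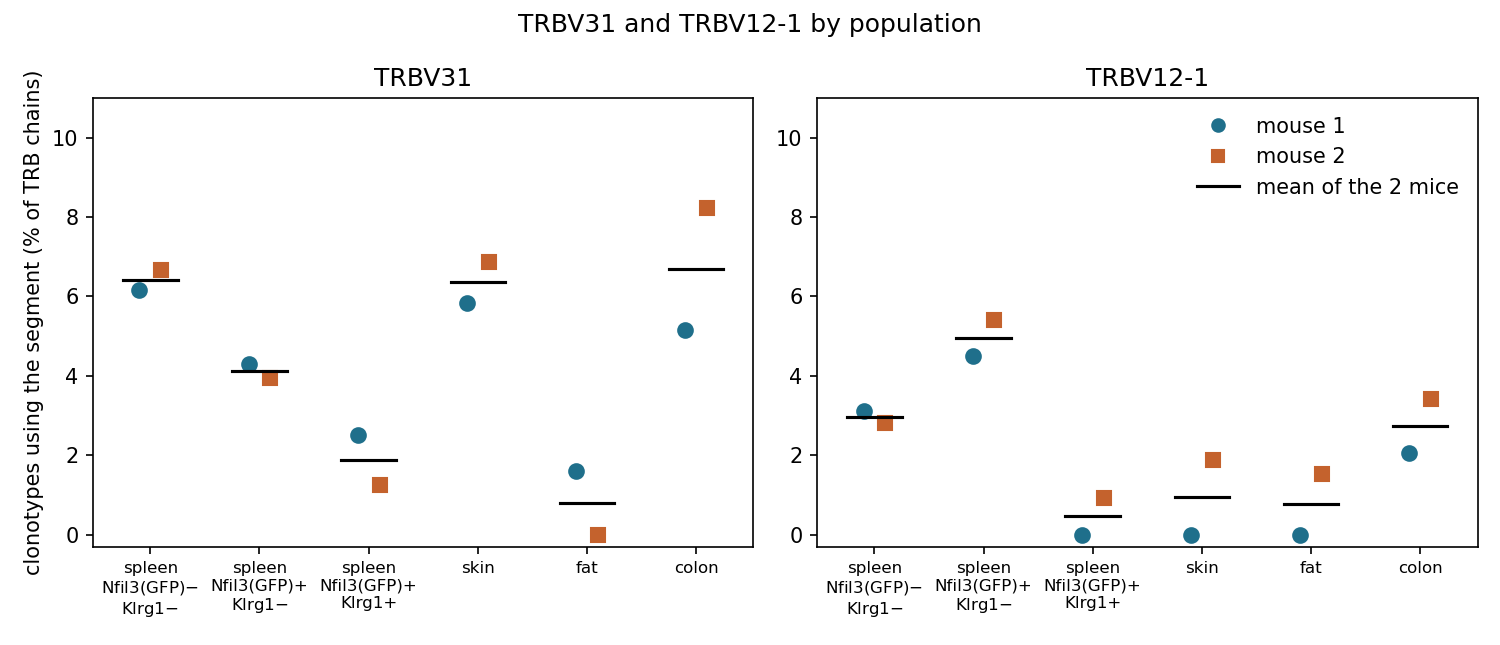
Percent of TRB chains of distinct clonotypes that use TRBV31 (left) or TRBV12-1 (right) in the 6 populations; circles are mouse 1, squares mouse 2, and lines their mean. TRBV31 lies at 6.42% in double-negative, 4.12% in progenitor and 1.87% in Klrg1-positive spleen cells, and TRBV12-1 at 4.95% in progenitor and 0.467% in Klrg1-positive spleen cells.

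Against Klrg1-positive spleen cells, skin had 0 segments past the threshold in edgeR (5 at an unadjusted p under 0.05) and 2 in DESeq2, TRBV1 (adjusted p = 0.0119) and TRBV31 (0.0321). TRBV1 (chromosome 6, 40891229 to 40891885) stood at 12.4 ± 7.21% in skin and 4.16 ± 2.36% in spleen (SD, n = 2; log2 fold change 1.66, SE 0.51, edgeR adjusted p = 0.165). TRBV31 stood at 6.36 ± 0.732% and 1.87 ± 0.887% (log2 fold change 1.80, SE 0.63, adjusted p = 0.205). TRAJ27 stood at 1.44 ± 0.646% and 4.19 ± 0.573% and TRAJ22 at 2.11 ± 1.19% and 5.59 ± 2.41% (adjusted p = 0.343 each). TRBV1 passed in edgeR without fat of mouse 1 (adjusted p = 0.0164) or of mouse 2 (0.0182), and over the 9 alternatives its adjusted p ran from 0.0119 to 0.942. With each distinct chain counted once its log2 fold change fell to 0.51 (edgeR adjusted p = 0.942), and with a library left out it ran from 0.90 without skin of mouse 2 to 2.31 without the Klrg1-positive spleen library of mouse 1.

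In fat 1 segment passed against Klrg1-positive spleen cells in edgeR (10 at an unadjusted p under 0.05), and it did not move the same way in both mice. TRAJ30 (chromosome 14, 54189866 to 54189924) made up 38.3% of fat TRA chains in mouse 1 and 1.25% in mouse 2, against 5.30 and 3.51% in spleen (log2 fold change 2.68, SE 0.56, edgeR adjusted p = 0.00436). The TRA of the dominant fat clonotype of mouse 1 uses it, in several combinations with other TRA chains that count as separate clonotypes. These combinations cannot give most of its counts. TRAJ30 was counted 71 times in fat of both mice together, and no TRB in fat of mouse 1 had more than 13 clonotypes. Most counts thus lay outside the clonotypes of any 1 TRB, and the cause was not tested. Without fat of mouse 1 the log2 fold change of TRAJ30 was -1.74, and with each distinct chain counted once it was 0.90 (edgeR adjusted p = 0.610). TRAJ31, also in the dominant fat clonotype, stood at 10.7 ± 13.4% and 4.77 ± 0.249% (adjusted p = 0.0729). TRAJ27 was seen in 1 of 263 fat chains against 27 of 653 in spleen (ratio 0.0920, exact counting interval 0.00225 to 0.558) and TRBJ2-2 in 2 of 189 against 34 of 561 (ratio 0.175, 0.0203 to 0.681), each with edgeR adjusted p = 0.0729. The call on TRAJ30 ended in DESeq2 (adjusted p = 0.0614, with 1 other segment passing; 7.86e-05 to 0.610 over the 9 alternatives) and without any 1 of the 6 spleen libraries (edgeR adjusted p 0.0632 to 0.167). Without fat of mouse 1, 12 segments passed, and without fat of mouse 2, 5, where TRAJ31 was among them at 2.24. With the mouse as a block 3 passed, TRAJ30, TRAJ27 and TRBJ2-2.

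Colon had 0 segments past the threshold against Klrg1-positive spleen cells in edgeR (2 at an unadjusted p under 0.05) and 1 in DESeq2. TRBV31 stood at 6.69 ± 2.17% in colon and 1.87 ± 0.887% in spleen (SD, n = 2; log2 fold change 1.88, SE 0.60, edgeR adjusted p = 0.234; DESeq2 adjusted p = 0.0234), higher in both mice, and passed with each distinct chain counted once (2.05, edgeR adjusted p = 0.0362; 0.0234 to 0.705 over the 9 alternatives). TRAJ12 stood at 2.35 ± 2.05% and 5.10 ± 2.72%, TRBV2 at 3.09 ± 1.45% and 7.75 ± 2.59%, and TRAJ27 at 7.41 ± 1.52% and 4.19 ± 0.573% (adjusted p = 0.655 each).

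Colon against skin also gave 0 segments in edgeR (4 at an unadjusted p under 0.05) and 1 in DESeq2. TRAJ27 (chromosome 14, 54192303 to 54192361) stood at 7.41 ± 1.52% in colon and 1.44 ± 0.646% in skin (SD, n = 2; log2 fold change 2.39, SE 0.64, edgeR adjusted p = 0.0576), higher in both mice. It passed with the mouse as a block (0.0309), with TMM (0.0466) and in DESeq2 (0.0262), and not with each distinct chain counted once (1.51, edgeR adjusted p = 0.753; 0.0262 to 0.895 over the 9 alternatives). TRBJ1-2 stood at 7.20 ± 1.44% and 1.93 ± 1.69%, TRAV4N-4 at 3.11 ± 1.87% and 7.63 ± 4.53%, and TRBV1 at 5.49 ± 0.984% and 12.4 ± 7.21%, and none passed. TRAV4N-4 has near-identical copies in the locus, so its share is uncertain between them. The TRBV1 difference vanished with each distinct chain counted once (log2 fold change 0.02).

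CDR3 measures were alike in most populations. Residues of the hydrophobic set at positions 6 and 7 of the TRB CDR3 numbered 0.480 ± 0.0397 per chain in fat and 0.243 to 0.301 in the other 5 populations (SD, n = 2; exact permutation test, p = 0.0311, adjusted p = 0.0829; with the mouse as a block p = 0.0694). The dominant fat TRBs count more than once there, as above. With each distinct chain counted once, fat stood at 0.377 ± 0.0244 and the others at 0.235 to 0.308 (exact permutation test, p = 0.0135, adjusted p = 0.0359). This alternative was chosen after seeing the data, was the only 1 of 4 to pass, and was not run with the mouse as a block. TRB CDR3 length was 13.4 ± 0.252 amino acids in fat and 13.5 to 13.6 elsewhere (exact p = 0.170, adjusted p = 0.291). Counted by cells, fat had instead the longest mean, 14.4 ± 1.29, with 15.3 in mouse 1 and 13.47 in mouse 2. The share of TRAJ 30 or lower ranged from 39.7 ± 24.3% in fat to 53.9 ± 0.572% in double-negative cells (exact p = 0.945) and that of TRBJ2 from 58.8 ± 4.54% in skin to 69.0 ± 17.7% in fat (exact p = 0.860), each with an adjusted p of 1. Without mouse 1 these spans widened from 14.3 to 33.7 points and from 10.2 to 25.9 points. Counted by cells, fat had the lowest mean TRBJ2 share in place of the highest, 54.0 ± 53.1%, with 16.5% in mouse 1 and 91.5% in mouse 2.

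Invariant receptor types were rare. Invariant NKT-type chains, which recognise lipids on CD1d, were found in 60 of 4267 kept double-negative cells of mouse 2 (1.41%, exact interval 1.07 to 1.81%) and in 4 of 4460 of mouse 1 (0.0897%, 0.0244 to 0.229%). The progenitor library had 2 of 1307 in mouse 1 and 0 of 3881 in mouse 2, which allows up to 0.0773%, and the Klrg1-positive spleen, skin, fat and colon libraries had 0. These zeros allow shares of up to 0.372% in fat of mouse 1 and, at the other end, 1.60% in colon of mouse 2. In mouse 2 the limit of colon lies above the share in its double-negative cells, so this zero does not show a lower share. The limits in mouse 1 were 0.929% in Klrg1-positive spleen cells, 1.48% in skin, 0.372% in fat and 1.13% in colon. All of these lie above the share in double-negative cells of mouse 1 (0.0897%), so none of the zeros of mouse 1 shows a lower share. Among all cells with a clonotype, those not kept included, the progenitor library of mouse 1 had 15 of 2255 (0.665%, 0.373 to 1.09%), that of mouse 2 had 3 of 7372, and the Klrg1-positive spleen library of mouse 1 had 2 of 514. Population means did not pass (exact permutation test, p = 0.182, adjusted p = 0.291). MAIT-type chains were found in 3 double-negative cells of mouse 2, 1 progenitor and 2 colon cells of mouse 1 and in no other library of mice 1 and 2 (exact permutation p = 1), where the limits run from 0.0673 to 1.60%. TRAV11, TRAJ18, TRAV1 and TRAJ33 were under the edgeR filter. In double-negative cells they made up 0.893 ± 0.879%, 2.94 ± 0.573%, 0.585 ± 0.118% and 2.37 ± 0.243% of TRA chains, and in progenitor cells 0.455 ± 0.261%, 2.17 ± 0.753%, 0.573 ± 0.208% and 3.26 ± 0.413%.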

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

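Every TRB chain with a constant segment call, 51163 in all, was listed with TRBC1 and 0 with TRBC2, including 33027 chains with a TRBJ2 segment, which lies downstream of TRBC1 in the locus; the constant calls were outside the comparisons, and this stood out in data not otherwise used. TRBJ1 and TRBJ2 chains alike carried this 1 call, so the calls cannot be read as the constant segment a chain used. The reference behind the calls was not examined, and the cause was not tested. Cells in clonotypes with more than 1 TRB or more than 2 TRA chains, which were not kept, made up 44.6% of the cells in skin of mouse 3, the highest share, and 7.65% in colon of mouse 2, the lowest, above what 0 cells would allow in every library. Droplets with 2 cells also give such clonotypes, and how many of these cells they account for was not tested.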

How the results depend on the processing

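Overlap within against between mice had the smallest possible p (0.03125) under all 6 alternatives, with overlap between mice 1 and 2 at or near 0, so this p says nothing about stability. The spans of the means of clonal expansion and diversity stayed past the threshold under 7 each. The overlap difference ranged from 0.00819 (Jaccard) to 0.0450, and expansion spanned 73.7 to 91.6 points. Single populations changed order: colon fell below Klrg1-positive spleen cells in expansion with the 3-cell bound (16.4 against 21.1%) and without thinning (38.89 against 38.95%), and in diversity without thinning (143.6 against 188.4); colon of mouse 2 rose above its skin in expansion with every paired clonotype (36.1 against 33.9%). Klrg1-positive minus double-negative sharing no longer passed without thinning (15.99 points, exact permutation p = 0.0556) and for skin and colon without thinning (10.01; chosen after seeing the data, as were fat left out, the 2-cell bound, chains counted once and merged copies), and ranged from 3.61 to 23.96 over the other alternatives; by single mice it was 7.547 and 25.55. Klrg1-positive minus progenitor stayed within its spread, from 2.83 to 22.4. Progenitor minus double-negative kept its sign and moved by more than its small spread: 1.18 with amino acids, 1.571 with TRB, 0.8738 with every paired and 0.7588 with every clonotype, 4.803 without thinning, 0.5907 by clonotypes, 1.659 without fat, 0.5537 with the 2-cell bound and 7.174 for skin and colon without thinning. Sharing between tissues moved to 26.74 with TRB and 2.539 by clonotypes. The mouse 3 difference moved to 23.14 with TRB, 7.634 with every paired and 8.429 with every clonotype, 23.4 without thinning and 7.361 by clonotypes; leaving out a mouse was not possible for it or for overlap within against between mice. Hydrophobic residues passed with chains counted once (span 0.1413). Leaving out a mouse gave spans of 15.69 to 33.72 for TRAJ and 8.497 to 25.91 for TRBJ2. Segment counts changed as follows. Progenitor minus double-negative gave 2 in DESeq2 and 1 with chains counted once, with or without block, and 0 to 3 with a library left out. Klrg1-positive minus progenitor gave 0 with block, TMM, cells, every clonotype and chains counted once, with or without block, and 0 to 1 with a library left out. Skin gave 2 in DESeq2 and 0 to 1 with a library left out. Fat gave 3 with block, 3 without filter, 35 (all lower) by cells, 2 with every clonotype, 0 with chains counted once, with or without block, 5 with copies merged and 0 to 12 with a library left out. Colon minus spleen gave 1 in DESeq2 and 1 with chains counted once, with or without block. Colon minus skin gave 1 with block, DESeq2, TMM and copies merged. Both colon counts stayed at 0 with any library left out, where the lone sample is assumed to vary like the other groups. Among 24 named segment values under 495 settings, 6 reversed: TRAJ30 in fat without fat of mouse 1 (range -1.74 to 3.30 over libraries left out), TRAJ31 in fat with chains counted once (-1.316; with block -1.32) and without fat of mouse 1 (-1.88 to 2.24), and TRBV1 in colon minus skin with chains counted once (0.02203; with block 0.01689). A further 22 no longer passed and 26 newly passed, in the same direction. Counting each chain once removes the combinations of 1 TRB with several TRAs, at 1.94 and 1.97 clonotypes per TRB in fat against 1.00 and 1.01 in double-negative cells. It equally removes repeats of 1 TRA with several TRBs, and most TRAJ30 counts in fat lay outside the clonotypes of any 1 TRB, as above. The share of each in the changes, and the cause of all other changes, was not tested. The smallest library sets the thinning depth, colon of mouse 2 (188 cells) for expansion and diversity and the inguinal node (110 cells) in mouse 3.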

Other observations

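Within the spleen, a larger share of Klrg1-positive cells had their clonotype among progenitor than among double-negative cells. With libraries thinned as above, 7.69% (mouse 1) and 30.5% (mouse 2) of Klrg1-positive spleen cells had their clonotype among the progenitor cells and 0.135 and 0.112% among the double-negative cells. By distinct clonotypes it was 5.18 and 11.6% against 0.121 and 0.101%. In the whole libraries it was 58 of 323 (18.0%, exact interval 13.9 to 22.6%) and 254 of 480 (52.9%, 48.3 to 57.5%) for progenitor cells, and 6 of 323 (1.86%, 0.685 to 3.999%) and 3 of 480 (0.625%, 0.129 to 1.82%) for double-negative cells. In mouse 3, at 110 cells per library, 41.3% of skin, 27.6% of colon, 6.36% of inguinal node and 1.33% of mesenteric node cells belonged to clonotypes of 2 or more cells. Mice 1 and 2 shared 11 amino acid clonotypes with mouse 3, of which 8 were in its mesenteric node, the largest library, 4 in colon, 1 in skin and 1 in the inguinal node; 3 were in the same tissue of both animals. Among these 3 was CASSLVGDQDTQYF with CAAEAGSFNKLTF, in 6 skin cells of mouse 2 and in 5 skin, 2 colon and 1 inguinal node cells of mouse 3.

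In the paragraphs that follow, the tests on the fat clone and on clonotypes shared between mice were chosen after the results were seen. The test on invariant chains was written before its result was seen.

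The TRB of the dominant fat clonotype of mouse 1 (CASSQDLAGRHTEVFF) also appeared in 3 spleen Klrg1-positive, 3 colon and 1 skin cell of that mouse among all cells with a clonotype. Carry-over at 1 rate into every library would give equal shares. Instead, 7 of 1288 cells of the 3 other Klrg1-positive libraries and 0 of 9487 double-negative and progenitor cells carried it (Fisher exact test, one-sided, p = 3.44e-07), nor did any of 36874 cells of mice 2 and 3. This p covers counting error in 5 libraries of 1 mouse, so it argues against 1 common rate and leaves open rates that differ between libraries. Fat cells carried into the Klrg1-positive libraries alone cannot be told apart from recirculating cells of the clone: the 4 next largest fat TRBs gave 3 cells there per 118 fat cells and the largest 4 per 660, among cells with 1 TRB (Fisher exact test, one-sided, p = 0.0781), which are too few. Cells of 1 clone in several organs of the animal, a biological explanation, may account for the pattern and was not tested. The fat share found in the spleen of mouse 1 rests on this clone.

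Double-negative cells of mouse 2 held 75 invariant NKT-type cells of 8884 (0.844%, exact interval 0.665 to 1.06%), against 5 of 7232 in mouse 1 (0.0691%, 0.0225 to 0.161%), where the progenitor library held 15 of 2255 (0.665%, 0.373 to 1.09%). If invariant NKT cells had passed the CD25 gate, which does not exclude them, their TRB chains would favour TRBV13-1, TRBV13-2, TRBV13-3, TRBV29 and TRBV1. Of the 60 kept cells, 49 (81.7%, 69.6 to 90.5%) used 1 of these 5, against 1316 of 4207 other cells (31.3%), an odds ratio of 9.79 (Fisher exact test, one-sided, p = 1.9e-15). The 60 cells were 60 distinct clonotypes, 56 with the TRA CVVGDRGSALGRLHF, and 27 used TRBV13-2. A candidate explanation is that this library holds some invariant NKT cells among the sorted Treg. Across the 6 populations the shares did not pass (exact permutation test, p = 0.182, adjusted p = 0.291), which does not show that the sorts are alike, and the difference between the mice was not tested.

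Mice 1 and 2 had 4 amino acid clonotypes in common, and each was found in the same population of both mice. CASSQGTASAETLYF with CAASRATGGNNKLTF was in colon (4 and 2 cells, and 1 colon cell of mouse 3), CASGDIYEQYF with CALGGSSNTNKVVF in skin (1 and 7, and 2 spleen Klrg1-positive cells of mouse 2), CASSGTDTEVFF with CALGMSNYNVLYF in double-negative (1 and 1) and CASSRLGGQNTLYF with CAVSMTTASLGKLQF in progenitor cells (1 and 1). Carry-over of cells between libraries would give identical nucleotides in all chains. The libraries of mice 1 and 2 had 0 such clonotypes in common, which speaks against carry-over of whole clonotypes. Each of the 4 nevertheless had 1 chain with the same nucleotides in both mice. It was the TRB of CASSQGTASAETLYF and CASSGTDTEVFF and the TRA paired with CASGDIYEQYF and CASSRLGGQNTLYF. Carry-over of single chains was not tested. Chance in proportion to clonotype numbers would put 47.1% of matches in the same population, and 4 of 4 were there (exact binomial test, one-sided, p = 0.0493; exact permutation of the populations of 1 mouse, 720 labelings, p = 0.00556). In the same tissue it would put 0.127% of matches, or 0.00507 of 4, and 2 were there, in colon and skin (exact binomial test, one-sided, p = 9.64e-06). These counts are above such chance, but both classes were set after the matches were seen and 4 clonotypes are few, so chance was not excluded.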
